A study of Mus musculus with 7 samples.

How the data were processed

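RNA-seq was run on mouse hippocampus, the brain region used for spatial and episodic memory, in 7 libraries. Per the labels, 3 libraries came from blank control mice (Control) and 4 from mice with noise-induced hidden hearing loss (NIHHL), a model in which noise damages hearing without the threshold loss seen in ordinary deafness. The noise was 110 dB for 2 h, and hippocampus was taken 1 month later. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads and fragmented, cDNA libraries were made with a NEBNext Ultra kit, and sequencing was on a Illumina NovaSeq instrument. Whether the libraries were strand-specific is not given in the sources used here. The labels number the samples within each group and name neither animals, sex, litter nor sequencing batch.

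The authors deposited a table of expected counts per gene, with an Ensembl identifier and, for most rows, a gene symbol. About 90.7% of its values were whole numbers and the rest carried decimals, as estimated counts do when reads shared between overlapping or similar genes are divided among them. The values were not scaled to library size. The submitters' processing notes name Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and DESeq2 without saying what each was used for. The genome build, the annotation and the counting step are not given in the sources used here. The table held 21965 genes, of which 90 had no symbol and 44 shared a symbol with another row. Rows without a symbol are treated as genes under their identifiers.

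The deposited expected counts were rounded to whole numbers. The total count per library ran from 14871376 in Control replicate 1 to 24515146 in Control replicate 2. Genes with too few counts were removed with edgeR's filterByExpr at its default minimum count of 10, which left 14417 genes holding 99.96% of all counts. Libraries were scaled by the trimmed mean of M values (TMM). CPM values, counts scaled to a common library size, use the TMM factors, and log2 CPM values carry a prior count of 2. Group means of CPM are given with the standard deviation (SD) over 3 Control and 4 NIHHL libraries. Counting intervals and floors cover counting error only, because the reads carry no molecular identifiers. For a gene with no count in any Control library, a fold was computed from the pooled NIHHL counts against 3 counts summed over the Control group, each scaled to library size. That fold leaves out counting error in NIHHL and the spread between libraries.

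NIHHL was compared with Control by edgeR's quasi-likelihood test with robust empirical Bayes moderation and group as the term in the model. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Log2 fold changes are NIHHL minus Control, with a standard error (SE) taken as the fold change divided by the square root of the F statistic. Values compared between single quantities, such as log2 CPM of Dnah11 or the mean log2 CPM of a gene list, were tested by an exact two-sided permutation test over all 35 splits of the 7 libraries into 3 and 4, whose smallest possible p is 0.0286. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

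Before the data were examined, 36 gene lists of 770 genes in all were written: the 2 themes that the series' design names (learning and memory, neurodegeneration), the family of the gene in its title (axonemal dynein heavy chains) with motile cilia of ependymal cells, hippocampal and glial cell types, neighbouring brain regions and tissues, and groups for stress, inflammation, clock, synapse, mitochondria and ribosomes. The genes of the learning and memory and neurodegeneration lists were chosen here and are not the authors' lists. The dynein and cilia lists were chosen because the series' title names Dnah11 as elevated, and Dnah11 is itself a member of the dynein list. Their choice therefore followed what the submitters reported for this series, and their results are not independent of that report. The 35 lists with at least 3 tested members, leaving out the Y-linked and Xist genes, were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list and fry, a rotation test of a list's own genes, were run beside it. Members were also adjusted over their list alone.

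The genes named in the text followed a rule fixed at the same time. It took Dnah11, up to 12 genes per direction past the threshold or, where fewer passed, the 6 per direction with the smallest unadjusted p without predicted gene models, the members of each described list that passed over all genes or over the list alone (at most 4) or otherwise the 2 with the smallest p, and Y-linked genes as a check of the animals' sex. The rule gave 45 genes, and 1 predicted gene model was passed over among the lower ones. Some of the genes that the rule gave are not reported here. The 16 lists described with their members are the 14 that camera called and the 2 themes of the series' design. Genes of other tissues named below were chosen after their values were seen.

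The test was tested on simulated counts drawn from the libraries' means, sizes and dispersions, with 200 of 14417 genes changed in each of 5 runs for the comparison of NIHHL with Control. About 14314 genes remained after the low-count filter was applied again. The test recovered 58.5% of genes changed 1.5-fold, 79.9% of those changed 2-fold and 95.0% of those changed 4-fold, and 7.88% of its calls were false. These counts were drawn independently around 1 mean per gene, without the differences in makeup between the libraries. The shares therefore do not measure how many such genes the test would find in the libraries themselves. Camera called a list shifted by 0.3 on the log2 scale in 5 of 5 runs. It called 0 of 170 lists that had not been shifted, but genes were drawn independently of each other, so this does not measure false list calls in the libraries, where the correlation estimated within a list reached 0.959 and the other splits of the libraries each gave 5 to 22 calls at the preset correlation.

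Alternatives written before the data were examined were other scaling factors, other low-count filters, no robust moderation, the replicate number as a block, leaving out each library in turn, limma-voom with sample quality weights, DESeq2's Wald test, other thresholds, and the other set tests. Added after the data were seen were an offset that removes each library's trend with transcript length, the choroid plexus score or the ependymal score as a covariate, and omitting both Control replicate 2 and NIHHL replicate 4. Transcript length was the longest annotated transcript in GENCODE M21 (GRCm38), matched by Ensembl identifier for 99.8% of tested genes. Because the authors' annotation is not stated, no coordinates from it are printed beyond a gene's chromosome.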

Results

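Hippocampal transcripts were counted in 3 Control and 4 NIHHL libraries, the latter 1 month after exposure to 110 dB noise for 2 h. Total counts were 14871376, 24515146 and 21032796 in Control replicates 1 to 3, and 21585796, 17285648, 18020201 and 16982202 in NIHHL replicates 1 to 4. Between 16292 and 16825 genes had at least 1 count in a library. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples.

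The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were expressed in both groups, at 48.8 ± 4.83, 16.4 ± 1.26, 23.0 ± 2.14 and 18.6 ± 1.02 CPM in Control and 47.6 ± 5.99, 16.9 ± 1.69, 23.2 ± 3.58 and 18.4 ± 1.20 CPM in NIHHL (mean ± SD). None of the 7 libraries lacked them. No gene among these differed between the groups (edgeR's quasi-likelihood test, lowest adjusted p = 0.996).

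The first question was which genes differ in the hippocampus after noise. Among the genes with the smallest p that were higher in NIHHL, Dnah6, a heavy chain of the axonemal dynein motor, was at 12.7 ± 1.75 CPM in NIHHL and 7.21 ± 1.55 in Control. Cfap91, a protein of the ciliary axoneme, was at 5.55 ± 0.791 against 3.35 ± 0.390 CPM, and Eno4, an enolase of the sperm flagellum, at 5.26 ± 0.915 against 2.75 ± 0.278 CPM. Among the lower genes, mt-Atp8, a mitochondrially encoded subunit of ATP synthase, was at 326 ± 32.1 CPM in NIHHL against 485 ± 35.3 in Control, and Htr7, a serotonin receptor, at 6.69 ± 0.503 against 9.73 ± 1.13 CPM (mean ± SD).

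None of these genes passed the test over all genes. Of 14417 genes, 0 were called by edgeR's quasi-likelihood test at an adjusted p under 0.05, and the smallest adjusted p was 0.472, for mt-Atp8. At an unadjusted p under 0.05 there were 523 genes, 334 higher and 189 lower, where 721 are expected by chance. The log2 fold changes were 0.81 (SE 0.16) for Dnah6, 0.72 (SE 0.17) for Cfap91, 0.93 (SE 0.19) for Eno4, -0.57 (SE 0.09) for mt-Atp8 and -0.55 (SE 0.13) for Htr7. The rule also named Rin2, a Ras and Rab interactor (log2 fold change 0.31, SE 0.07), and, lower in NIHHL, the prohormone convertase Pcsk1 (-0.38, SE 0.10), the keratin Krt12 (-0.70, SE 0.19), Tceal6 (-0.36, SE 0.10) and Mphosph10 (-0.34, SE 0.10). Each had an adjusted p of 0.996 by edgeR. The values of the groups did not overlap for 750 genes, 5.20% of those tested, and chance gives 5.71%.

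Hsd3b1, an enzyme of steroid hormone synthesis, and Akr1cl, an aldo-keto reductase, had no count in any Control library. Hsd3b1 had 81, 26, 41 and 9 counts in NIHHL replicates 1 to 4 and Akr1cl had 23, 13, 16 and 3. Against 3 counts summed over the Control group, the pooled NIHHL counts gave a 42.8-fold higher level for Hsd3b1 and a 14.99-fold higher level for Akr1cl. These folds are not lower bounds, because they leave out the spread between NIHHL libraries, and replicate 4 had only 9 and 3 counts. By edgeR both genes had an adjusted p of 0.996. Both belong to families of similar genes among which reads can be divided, though their deposited counts were whole numbers in every library. Reads carried over between samples or assigned to the wrong library were not tested for, so the levels of both genes and these folds are uncertain.

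DESeq2's Wald test was run on all 21965 genes with its own low-count filter, so its counts and those of edgeR cover different sets of genes. It left 3788 genes without an adjusted p. At an unadjusted p under 0.05 it had 447 genes, and it called 4 genes, 3 higher and 1 lower. They were mt-Atp8 (log2 fold change -0.57, SE 0.09, adjusted p = 1.50e-05), Hsd3b1 (adjusted p = 3.86e-05), Akr1cl (adjusted p = 0.0392) and Dnah6 (0.81, SE 0.18, adjusted p = 0.0471). The reading frame of mt-Atp8 overlaps that of mt-Atp6, whose log2 fold change was -0.15 (SE 0.07) by edgeR. The deposited counts of mt-Atp8 were whole numbers in every library, but how reads were assigned between mt-Atp8 and mt-Atp6 was not tested.

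The second question concerned Dnah11, which the series' title names as elevated. Dnah11 (ENSMUSG00000018581, chromosome 12 in the GRCm38 annotation) encodes a heavy chain of the outer dynein arm of motile cilia. Its level was 5.26 ± 1.70 CPM in NIHHL and 3.15 ± 0.587 CPM in Control, a 1.68-fold difference. Control replicates 1 to 3 stood at 3.44, 2.48 and 3.54 CPM, and NIHHL replicates 1 to 4 at 6.95, 6.44, 3.41 and 4.25 CPM. NIHHL replicate 3 lay within the range of the Control libraries and the other 3 NIHHL libraries lay above it.

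By edgeR's quasi-likelihood test the log2 fold change of Dnah11 was 0.75 (SE 0.26, 95% interval 0.18 to 1.33) and ranked 132 of 14417 by p, with p = 0.0148 before adjustment and 0.996 after it, beside p = 0.143 by the exact two-sided permutation test of log2 CPM over 35 splits. DESeq2 gave a log2 fold change of 0.75 (SE 0.29) with an adjusted p of 1.00. The deposited counts behind these values were between 51.3 and 151 per library and carried decimals. Dnah11 shares 642 exon bases with Cdca7l on the opposite strand, and without strand information reads there cannot be assigned; Cdca7l stood at 0.988 CPM in NIHHL and 1.19 in Control.

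The axonemal dynein heavy chains, the motors that bend motile cilia, had a higher mean in NIHHL in 15 of 16 tested members, with a median log2 fold change of 0.38. Dnah6, Dnah9 and Dnah2 passed when adjusted over the list alone, and 0 members passed over all genes. Dnah9 was at 26.2 ± 1.43 CPM in NIHHL against 20.04 ± 2.12 in Control and Dnah2 at 6.40 ± 1.296 against 4.21 ± 0.493 CPM, and in each of the 3 genes every NIHHL library lay above every Control library. These 3 genes had the smallest p of the list, so this separation follows in part from how they were picked. Dnah11 had an adjusted p of 0.0591 over the list alone (edgeR). The near-identical paralogs Dnah7a, Dnah7b and Dnah7c are members whose reads can be divided among them.

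Motile cilia genes of ependymal cells, which line the ventricles, showed the same direction in 25 of 27 members, with a median log2 fold change of 0.49. Ak7, an adenylate kinase of cilia, was at 10.5 ± 1.24 CPM in NIHHL against 6.47 ± 1.43 in Control, and Cfap44, an axonemal protein, at 7.50 ± 0.728 against 5.21 ± 0.526 CPM. These 2 members passed when adjusted over the list alone and 0 over all genes. Foxj1, the master regulator of motile ciliogenesis, was at 17.8 ± 1.26 CPM against 11.3 ± 3.84 and did not pass; it was named after its value was seen.

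Both lists were chosen because the series' title names Dnah11 as elevated, so their tests are not independent of that report. Camera at its preset correlation called both lists, with an adjusted p of 1.63e-16 for ependymal motile cilia and 4.31e-10 for axonemal dyneins. Neither call held otherwise: adjusted p = 0.176 and adjusted p = 0.267 with an estimated correlation. The exact permutation test of the mean log2 CPM gave p = 0.0857 for the ependymal list and p = 0.0571 for the dyneins, both 0.429 after adjustment over the 35 lists. The median of the dynein list was 0.74 without Control replicate 3, 0.59 with the ependymal score as a covariate and 0.22 omitting both Control replicate 2 and NIHHL replicate 4, and the preset call held in each. The 6 members of all lists that passed over their list alone became 15 without Control replicate 2, 24 without Control replicate 3 and 3 without NIHHL replicate 2.

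**Figure D1:**
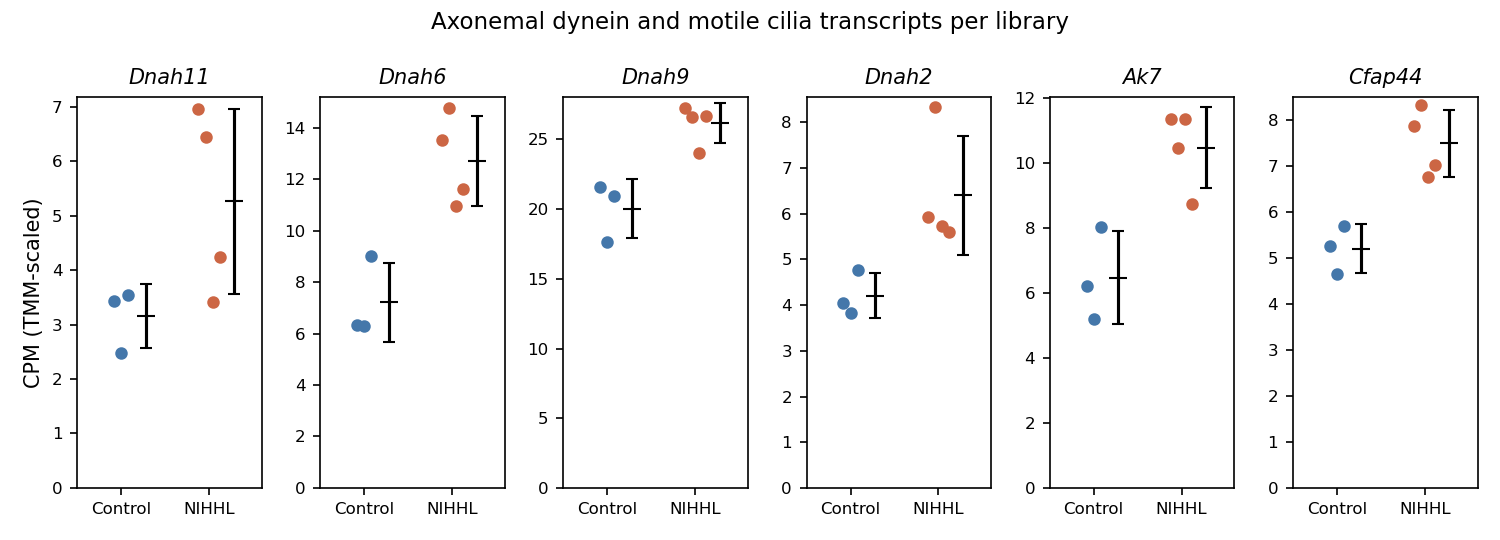
TMM-scaled CPM of 4 axonemal dynein genes and 2 ependymal cilia genes; each dot is 1 library (blue, 3 Control; orange, 4 NIHHL) and the black marks are the group mean with its SD. For Dnah6, Dnah9, Dnah2, Ak7 and Cfap44 every NIHHL dot is above every Control dot, whereas for Dnah11 NIHHL replicate 3, at 3.41 CPM, lies within the Control range. Genes other than Dnah11 are those with the smallest p of their lists, so their separation follows in part from how they were picked.

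Several glial and immune lists had smaller upward medians. Of 20 oligodendrocyte genes 18 were higher in NIHHL, with a median log2 fold change of 0.18; the myelin genes Mog and Mobp had log2 fold changes of 0.23 (SE 0.08) and 0.23 (SE 0.09). Of 23 inflammation genes 19 were higher (median 0.15), among them the complement component C3 at 4.32 ± 2.02 CPM against 2.08 ± 0.451 and Gpnmb, a glycoprotein of activated phagocytes, at 6.78 ± 1.96 against 4.52 ± 0.0771 CPM. Of 24 interferon-response genes 22 were higher (median 0.19), with a log2 fold change of 0.51 (SE 0.21) for Oasl2, an oligoadenylate synthetase-like protein. All 19 astrocyte genes were higher (median 0.07), with 0.30 (SE 0.09) for Vim and 0.30 (SE 0.10) for Sox9.

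Camera at its preset correlation gave adjusted p = 3.36e-09 for oligodendrocyte, 9.09e-05 for inflammation, and 0.000181 for both interferon-response and astrocyte genes. With an estimated correlation none was called (adjusted p = 0.374, 0.176, 0.176 and 0.596), and 0 of their members passed over all genes or over the list alone. The inflammation score, the mean log2 CPM of the list, was 2.16 ± 0.0388 in NIHHL and 1.86 ± 0.114 in Control, with every NIHHL library above every Control library; its exact permutation p was 0.0286, the smallest possible, and 0.429 after adjustment over 35 lists. Without Control replicate 2 the astrocyte call ended (median 0.05, adjusted p = 0.0760), and its median was 0.11 without NIHHL replicate 4. The oligodendrocyte median was 0.27 without Control replicate 3, and the inflammation median 0.10 without Control replicate 1 and 0.07 without NIHHL replicate 3. With the ependymal score as a covariate the inflammation, interferon and astrocyte calls ended (adjusted p = 0.172, 0.601 and 0.0757), at medians of 0.16, 0.16 and 0.07. Microglia genes, 11 of 19 higher, were not called with all 7 libraries (adjusted p = 0.770), and were called without NIHHL replicate 4 (0.06, 0.0275). Without that library the log2 fold change of C3 went from 1.04 to 0.67 and that of Gpnmb from 0.58 to 0.37.

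All 13 mitochondrially encoded genes were lower in NIHHL, with a median log2 fold change of -0.11; mt-Atp8 alone passed when adjusted over the list alone. Presynaptic genes were lower in 21 of 25 cases (median -0.08), among them syntaxin Stx1a at 61.1 ± 5.40 CPM against 73.0 ± 3.43 and complexin Cplx1 at 450 ± 20.99 against 507 ± 13.4 CPM. Nuclear genes of oxidative phosphorylation were lower in 31 of 32 cases (median -0.13), such as Sdhb of complex II (-0.16, SE 0.10) and Cox7a2 of cytochrome oxidase (-0.20, SE 0.13). Immediate early genes, which neuronal activity switches on, were lower in 21 of 29 cases (median -0.12), such as Junb (-0.29, SE 0.12) and Egr2 (-1.10, SE 0.45).

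The preset camera test called these 4 lists, with adjusted p = 4.79e-07 for mitochondrially encoded, 2.49e-06 for presynaptic, 9.58e-06 for nuclear oxidative phosphorylation and 0.00200 for immediate early genes. With an estimated correlation none was called (adjusted p = 0.266, 0.267, 0.660 and 0.660). The mitochondrially encoded score had an exact permutation p of 0.0286 before and 0.429 after adjustment over 35 lists. The oxidative phosphorylation call ended without Control replicate 2 (median 0.0037, adjusted p = 0.958) and without NIHHL replicate 4 (-0.05, 0.122), with a median of -0.23 without Control replicate 1. It also ended by limma-voom (-0.03, 0.240), and the median was -0.45 with the ependymal score as a covariate (1.86e-31). The immediate early call ended without Control replicate 3 (-0.0025, 0.971) and without NIHHL replicate 1 (-0.06, 0.521), with a median of -0.18 without Control replicate 1. Egr2 went to -0.63 without Control replicate 3. The mitochondrially encoded median was -0.06 without Control replicate 2, and a correction for transcript length ended that call (-0.06, adjusted p = 0.104). The ependymal score as a covariate ended the presynaptic and immediate early calls (medians -0.02 and -0.05, adjusted p = 0.964 and 0.941).

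Dentate granule cell genes were higher in 15 of 16 cases (median 0.14), with a log2 fold change of 0.33 (SE 0.12) for Glis3 and 0.25 (SE 0.09) for Sipa1l2. Camera's adjusted p was 0.000141 at the preset correlation, and adjusted p = 0.660 with an estimated correlation. Without Control replicate 3 it was 0.202 with a median of 0.08, and the median was 0.25 without Control replicate 1. Omitting both Control replicate 2 and NIHHL replicate 4 also ended the call (0.12, 0.0616). Genes of CA1 pyramidal cells were higher in 7 of 13 cases and those of CA2 and CA3 pyramidal cells lower in 11 of 16, and neither list was called (adjusted p = 0.599 and 0.267). The CA2 and CA3 list was called without Control replicate 3 (-0.16, adjusted p = 0.000204) and without NIHHL replicate 4 (-0.13, 0.00740).

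Cytosolic ribosomal protein genes were lower in 38 of 40 cases (median -0.11), for example Rplp2 (-0.16, SE 0.12) and Rpl4 (-0.11, SE 0.09). The preset adjusted p was 2.57e-05 and adjusted p = 0.671 with an estimated correlation. The share of counts in these genes was lowest in NIHHL replicate 4, at 0.682%, and highest in Control replicate 2, at 1.10%. Leaving out Control replicate 2 turned the median to 0.0350 (adjusted p = 0.687), and leaving out NIHHL replicate 4 brought it to -0.0058 (adjusted p = 0.977); it was -0.23 without Control replicate 1 and -0.17 without NIHHL replicate 1. Limma-voom ended the call (-8.48e-04, adjusted p = 0.900), and with the ependymal score as a covariate the median was -0.58 (9.34e-51). The same 2 libraries stood at opposite ends of a trend with transcript length, with Control replicate 1 near NIHHL replicate 4. The Spearman correlation was taken between a gene's log2 deviation from the mean of the libraries and its length. It covered genes with a mean log2 CPM above 4, which are not independent replicates. The correlation was -0.65 in Control replicate 2, 0.59 in NIHHL replicate 4 and 0.50 in Control replicate 1.

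Choroid plexus genes, from the tissue that secretes cerebrospinal fluid, were higher in NIHHL in 20 of 20 cases (median log2 fold change 0.71), and 0 passed. Prlr, the prolactin receptor, was at 31.5 ± 20.7 CPM in NIHHL and 15.8 ± 14.2 in Control, and Tmem72 at 139 ± 34.6 against 114 ± 10.98 CPM. The share of counts from Ttr, the main choroid plexus transcript, was 0.00561%, 0.638% and 0.129% in Control replicates 1 to 3 and 0.788%, 0.0490%, 0.439% and 0.386% in NIHHL replicates 1 to 4. Camera's preset adjusted p was 6.07e-07, with adjusted p = 0.660 with an estimated correlation, and the exact permutation p of the score was 0.429. Without Control replicate 1 the median was 0.22 (adjusted p = 0.458), without NIHHL replicate 1 it was 0.22 (adjusted p = 0.00504), and without Control replicate 2 it was 2.12. With the ependymal score as a covariate the call ended and the median turned to -0.36 (adjusted p = 0.414).

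Meningeal fibroblast genes were higher in 13 of 17 cases (median 0.16), with a log2 fold change of 0.45 (SE 0.23) for Ogn and 0.29 (SE 0.18) for Mgp. The preset adjusted p was 0.0270, with adjusted p = 0.660 with an estimated correlation. The call ended without Control replicate 1 (0.447), without Control replicate 2 (median 0.04, 0.334) and without NIHHL replicate 1 (0.521), and the median was 0.40 without Control replicate 3 and 0.31 without NIHHL replicate 4. It also ended with library totals (adjusted p = 0.0606), by limma-voom (0.09, 0.402), with the choroid plexus score as a covariate (0.0991), with the ependymal score as a covariate (-0.09, 0.854) and omitting both Control replicate 2 and NIHHL replicate 4 (0.0962).

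**Figure D2:**
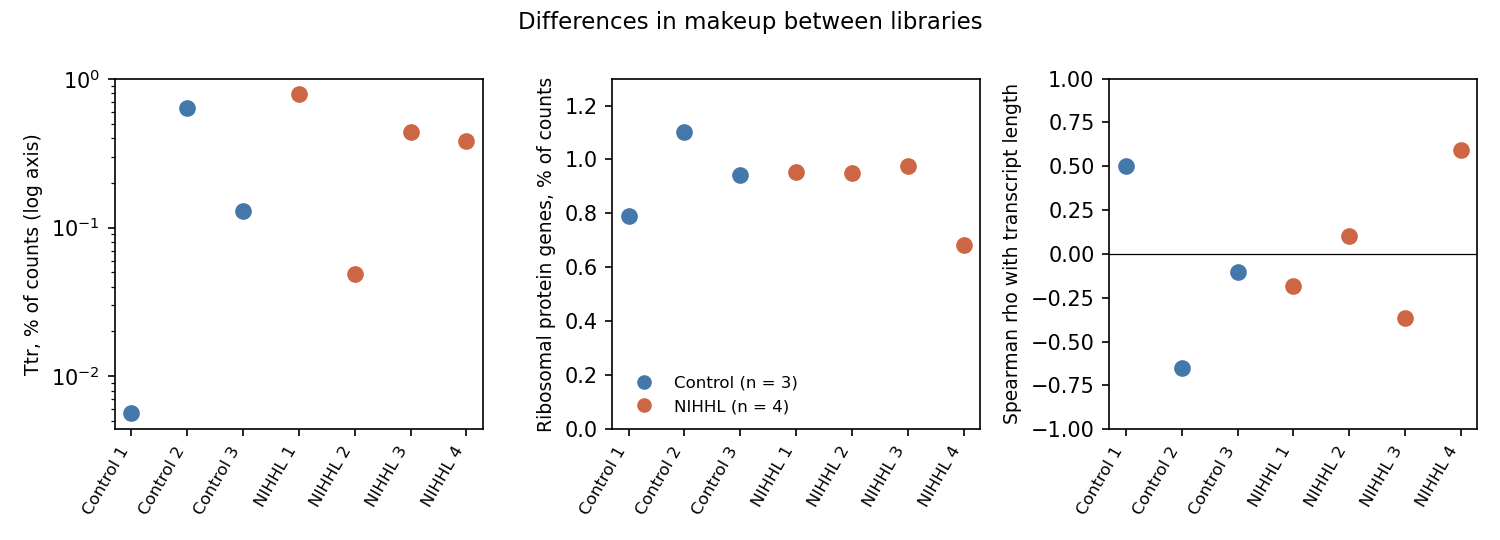
The percentage of counts from Ttr (log axis), the percentage from 40 cytosolic ribosomal protein genes, and the Spearman correlation across genes with transcript length, each for the 7 libraries (blue, Control; orange, NIHHL). The correlation covers genes with a mean log2 CPM above 4. Ttr is lowest in Control replicate 1 and highest in NIHHL replicate 1, and both Control replicate 2 and NIHHL replicate 4 stand at the ends of the other 2 measures.

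The series' design names learning or memory and neurodegenerative disease as the themes used to select genes. Of 81 learning and memory genes 45 were higher and 36 lower in NIHHL, with a median log2 fold change of 0.00; camera's direction and the mean score were slightly downward. Htr7 and Egr2 had the smallest p, and 0 members passed over all genes or over the list alone. Of 75 neurodegeneration genes 33 were higher and 42 lower (median -0.01). Wnt2, a Wnt ligand, had the smallest p among them (0.64, SE 0.21), at 4.43 ± 0.631 CPM in NIHHL against 2.84 ± 0.788 in Control. Camera called neither list at the preset correlation (adjusted p = 0.770 and 0.311).

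The remaining lists were not called by camera at its preset correlation with all 7 libraries. Upward medians were found for oligodendrocyte precursors (10 of 12 higher, adjusted p = 0.0677), newborn and dividing neurons (10 of 17, 0.206), ventral hippocampus (6 of 10, 0.380), thalamus and habenula (10 of 19, 0.532), hypothalamus and pituitary (2 of 3, 0.457), postsynaptic glutamate genes (23 of 33, 0.809) and the glucocorticoid response (11 of 20, 0.985). Downward medians were found for endothelium (5 of 16 higher, 0.147), mural cells (4 of 12, 0.599), cortex (4 of 18, 0.206), striatum (7 of 17, 0.848), GABA receptors (4 of 15, 0.206), GABA neurons (10 of 22, 0.417), endoplasmic reticulum and heat stress (9 of 21, 0.532), clock genes (9 of 18, 0.718) and blood (2 of 6, 0.931). Leaving out 1 library brought calls to some of them: without Control replicate 1, oligodendrocyte precursors (0.15, adjusted p = 0.00881), postsynaptic genes (0.06, 0.00478) and blood (-0.34, 0.0223); without Control replicate 2, cortex (-0.14, 0.000559), GABA receptors (-0.07, 0.0107) and clock genes (-0.06, 0.0408). Endothelium was called without Control replicate 3 (-0.11, 0.0114) and without NIHHL replicate 4 (-0.05, 0.0437), GABA receptors also without NIHHL replicate 4 (-0.06, 0.0105), and oligodendrocyte precursors without NIHHL replicate 2 (0.12, 0.0362). For microglia, striatum and blood the median and the difference of the mean score had opposite signs.

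**Figure D3:**
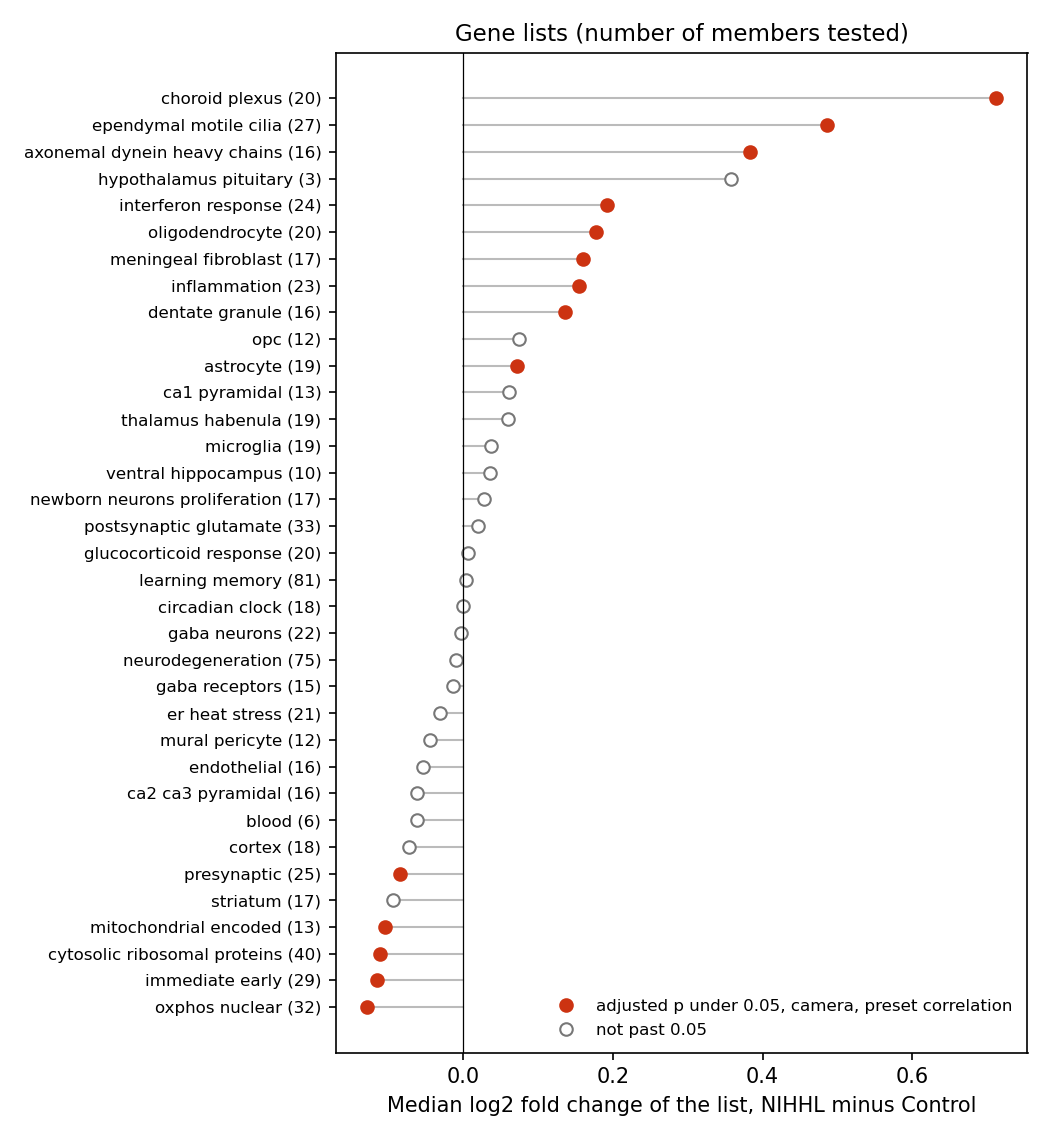
Median log2 fold change (NIHHL minus Control) of each of 35 gene lists, with the number of tested members in parentheses; filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. The 14 filled lists run from -0.13 for nuclear oxidative phosphorylation to 0.71 for choroid plexus; with an estimated correlation 0 of them pass.

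Transcripts of tissues outside the brain were also counted, in genes chosen after their values were seen. Whether these reads came from the hippocampal samples or were carried over from others, in the tube or by index hopping during sequencing, was not tested. Gkn1, a gastrokine of the stomach lining, had 411, 0 and 575 counts in Control replicates 1 to 3 and 3, 416, 483 and 55 in NIHHL replicates 1 to 4. Iapp, the islet amyloid peptide of pancreatic beta cells, had 406, 53 and 587 counts in Control and 552, 412, 400 and 145 in NIHHL. Alb, serum albumin of the liver, had 0, 1 and 0 counts in Control and 0, 29, 0 and 302 in NIHHL. Cyp11a1, the first enzyme of steroid synthesis, had 21, 17 and 23 counts in Control and 95, 50, 46 and 9 in NIHHL.

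**Figure D4:**
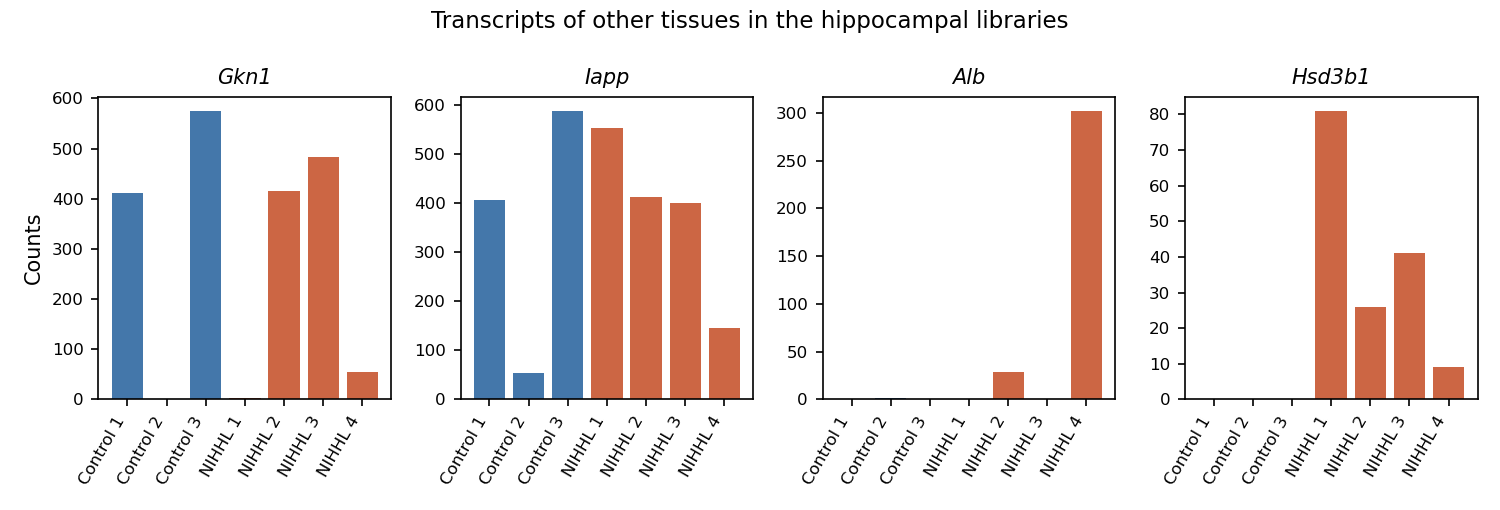
Counts of Gkn1, Iapp, Alb and Hsd3b1 in each of the 7 libraries (blue, Control; orange, NIHHL). Gkn1 is near 0 in Control replicate 2 and NIHHL replicate 1, Alb is highest in NIHHL replicate 4, and Hsd3b1 has counts in NIHHL libraries alone.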

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

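Every value in this part was measured by a check set out in advance, which compares the gap between 1 library and its nearest neighbour with the whole range of the 4 NIHHL libraries. Of 84 gene levels, list scores and library measures checked, 8 had 1 NIHHL library far from the other 3, where chance gives about 1 in 20 for independent values. The values here are not independent, since most of the 8 lay in NIHHL replicate 4 and some rest on the same genes. The number 8 therefore does not show an excess over chance. In NIHHL replicate 4 the gap filled 0.9644 of the range for Stx1a (log2 CPM 5.73), 0.902 for the presynaptic score (8.48), 0.8828 for the ribosomal protein score (7.12), 0.9165 for the share of counts from ribosomal protein genes (0.682%), 0.8797 for the cortex score (3.98) and 0.8323 for the striatum score (2.13). It was 0.8546 for Dnah2 in NIHHL replicate 2 (log2 CPM 3.08) and 0.8702 for Sipa1l2 in NIHHL replicate 1 (6.31). The presynaptic score of NIHHL replicate 4 lay above those of the other NIHHL libraries, and its Stx1a, ribosomal, cortex and striatum values below them. Dnah2 was higher in NIHHL replicate 2, and Sipa1l2 lower in NIHHL replicate 1, than in the other NIHHL libraries. No explanation was tested for these values.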

How the results depend on the processing

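The length offset, the choroid plexus and ependymal covariates and the omission of both Control 2 and NIHHL 4 were chosen after seeing the data. Of the planned settings, 18 gave a count of genes past the threshold, which was 0 in each except DESeq2 (4). Dnah11 stayed higher in NIHHL and short of the adjusted threshold in the 16 planned settings that gave it a value, at log2 fold changes of 0.58 to 0.91, and in the 4 added ones, at 0.60 to 0.84. The ependymal covariate gave 306 genes (46 higher, 260 lower), in a fit with 4 residual degrees of freedom whose score correlated with group at 0.756. Omitting both libraries gave 1 gene, Gcat, whose symbol stands on 2 entries. The cause was not tested for any change below. Values are log2 fold changes of genes, medians of lists, or counts.

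Camera with an estimated correlation and fry each called 0 lists. Adjusted p was 0.267 and 0.388 for axonemal dyneins (median 0.3825) and 0.176 and 0.233 for ependymal cilia (median 0.4858). Both tests used the same fit, so the medians could not change. Members past the threshold over their list alone, 6 as reported, numbered 10 with no low-count filter, 10 with the replicate block, 13 by limma-voom, 18 by DESeq2, 20 with the length offset, 22 with the choroid covariate, 114 with the ependymal covariate and 27 omitting both libraries.

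These values changed sign. Upper-quartile factors: clock 3.27e-04. Library totals: Eif2s3y 1.79e-04, clock 0.0165, GABA neurons 0.0168, GABA receptors 0.0038, neurodegeneration 0.0075. No filter: hypothalamus and pituitary -0.1230. CPM of 1 in 3 libraries: clock 0.0020, GABA neurons 4.94e-04. Limma-voom: Kdm5d -0.0442, blood 0.0639, CA1 -0.0235, learning and memory -0.0104. Length offset: Kdm5d -0.0369, blood 0.0641, glucocorticoid -0.0115, learning and memory -0.0215, postsynaptic -0.0218. Choroid covariate: clock 0.0117, GABA receptors 0.0208, glucocorticoid -0.0587, mural 0.0339, thalamus -0.0362, ventral hippocampus -0.0394. Ependymal covariate: Ogn -0.1717, Ddx3y 0.01, CA2 and CA3 0.0055, choroid plexus -0.3630, clock 0.0027, endothelium 0.0359, GABA receptors 0.0454, glucocorticoid -0.1568, meninges -0.0884, microglia -0.0574, mural 0.1718, neurodegeneration 0.0544, thalamus -0.0789. Omitting both libraries: Rplp2 0.0014, Rpl4 0.0164, Sdhb 0.0086, Kdm5d -0.0844, Eif2s3y 0.0300, blood 0.5833, ribosomal 0.1476, learning and memory -0.0345, newborn neurons -0.0196, oxidative phosphorylation 0.0746, postsynaptic -0.0527. The learning and memory list passed camera at its preset correlation with the ependymal covariate (0.0963, adjusted p = 0.00836) and omitting both libraries (adjusted p = 0.0136), in opposite directions, and neurodegeneration passed omitting both (-0.0496, adjusted p = 0.0255).

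Other lists not called as reported passed camera by limma-voom (GABA receptors -0.10, adjusted p = 0.00682), with the choroid covariate (newborn neurons 0.08 and oligodendrocyte precursors 0.10, both 0.0444), with the ependymal covariate (oligodendrocyte precursors 0.27, 0.0135; blood -1.31, 1.79e-17; postsynaptic 0.15, 1.75e-05) and omitting both libraries (clock -0.07, 0.0460; cortex -0.10, 0.0198; GABA receptors -0.11, 0.000283; hypothalamus and pituitary 0.67, 0.0304). Omitting both, and besides learning and memory, 4 of the sign changes given above also passed: ribosomal (2.09e-10), oxidative phosphorylation (0.00103), blood (0.00615) and postsynaptic (0.00190). Ribosomal and oxidative phosphorylation genes were thus called higher in NIHHL there, opposite to the calls with all 7 libraries.

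Lists that stayed called moved by over 1.5 times as follows. Choroid covariate: astrocyte 0.12, ribosomal -0.18, dentate granule 0.25, oxidative phosphorylation -0.20. Ependymal covariate: axonemal dyneins 0.59, ribosomal -0.58, dentate granule 0.37, mitochondrially encoded -0.19, oxidative phosphorylation -0.45. CPM of 1 in 3 libraries: inflammation 0.08. Length offset: ribosomal -0.07, oxidative phosphorylation -0.09. Limma-voom: choroid plexus 1.26, immediate early -0.22, inflammation 0.26. Omitting both libraries: astrocyte 0.11, axonemal dyneins 0.22, choroid plexus 2.00, immediate early -0.24, presynaptic -0.13. Of the named genes, mt-Atp8 (-0.62), Rplp2 (-0.51), Sdhb (-0.44), Cox7a2 (-0.58) and Sipa1l2 (0.47) passed over all genes with the ependymal covariate.

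With the replicate block 0 genes and 15 lists passed. The oxidative phosphorylation (-0.04, adjusted p = 0.124) and ribosomal calls (0.856) were lost there, and calls came for CA2 and CA3 (-0.12, 0.00785), GABA receptors (-0.07, 0.00908) and microglia (0.07, 0.0307). The same calls were lost and gained without NIHHL replicate 4, where endothelium was called as well, so they cannot be credited to the blocking. Medians moved by over 1.5 times for astrocyte (0.11), inflammation (0.26) and meningeal genes (0.34), which stayed called. In their deviations from the group mean, same-numbered samples correlated at -0.448, -0.445 and 0.0612, and not every sample correlated best with its own number. Expression therefore showed no pairing by number. This does not exclude a litter or batch shared by same-numbered samples, which the labels do not name. With the replicate block the sign changed for Kdm5d -0.0637, blood 0.1852, clock 0.0075, cortex 0.0205, ribosomal 0.0081, glucocorticoid -5.00e-04, learning and memory -0.0140 and postsynaptic -0.0126.

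Leaving out 1 library at a time gave 12 to 16 lists, 3 to 24 members, and these ranges: learning and memory -0.0131 to 0.0350, neurodegeneration -0.0327 to 0.0064, blood -0.3851 to 0.3950, CA1 -0.0588 to 0.0835, CA2 and CA3 -0.1567 to 0.0188, clock -0.0578 to 0.0438, cortex -0.1354 to 0.0389, ribosomal -0.2306 to 0.0350, stress -0.0649 to 0.0163, GABA receptors -0.0679 to 0.0098, glucocorticoid -0.0874 to 0.0816, hypothalamus and pituitary -0.1412 to 0.5717, microglia -0.0296 to 0.0579, mural -0.1231 to 0.0704, oxidative phosphorylation -0.2281 to 0.0037, postsynaptic -0.0192 to 0.0622, striatum -0.1214 to 0.0356, thalamus -0.0650 to 0.0599, Ddx3y -0.1165 to 0.0440, Eif2s3y -0.0555 to 0.0298, Kdm5d -0.0537 to 0.0982 and Uty -0.0267 to 0.1020. Named genes short of the threshold that moved by over 1.5 times were Prlr (0.56 without Control replicate 1, 1.99 without Control replicate 2, 0.54 without NIHHL replicate 1), Tmem72 (0.17 without NIHHL replicate 1), Ogn and Mgp (0.22 and 0.14 without Control replicate 1, 0.69 and 0.54 without Control replicate 3), Cox7a2, Sdhb and Rplp2 (-0.34, -0.25 and -0.25 without Control replicate 1, -0.08, -0.04 and -0.09 without Control replicate 2), Cox7a2 and Rplp2 (-0.13 and -0.06 without NIHHL replicate 4) and Rpl4 (-0.06 without Control replicate 2, -0.04 without NIHHL replicate 4). The ependymal cilia list stayed past the preset threshold in each (0.36 to 0.57).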

Other observations

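The tests with the ependymal and choroid covariates, of choroid markers, of adrenal, testis and gastric genes and of choroid differences between groups were chosen only after the result was seen. With 0 genes called by edgeR for NIHHL against Control (523 at an unadjusted p under 0.05; 4 by DESeq2, 0 by limma-voom), each of the 35 splits of the 7 libraries reaches that number, so this count of 35 decides nothing. The highest other split gave 58, parting Control 1, Control 3 and NIHHL 2, the libraries with the least Ttr, from the rest, which points to a structure of the samples. For gene lists 8 of the 35 splits gave at least the 14 called, the highest other being 22, so chance is not excluded.

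Dnah11 and 14 other axonemal dyneins of the 16 tested had a higher mean in NIHHL, and 0 passed over all genes. A trend with transcript length is argued against as the whole cause: once it was removed Dnah11's log2 fold change was 0.70 (0.696, SE 0.25) and the dynein median 0.3271. Choroid plexus carried along is argued against too, since Dnah11 stood at 0.8427 (SE 0.28) with that score as a covariate. With the ependymal score as a covariate Dnah11 was at 0.6043 (SE 0.42). In the same fit the dynein median was 0.5880, above the 0.3825 without it, and camera's preset call held (adjusted p = 0.000808). That fit had 4 residual degrees of freedom, and camera at its preset correlation also called blood genes there (median -1.31, adjusted p = 1.79e-17). The dynein call in it therefore does not separate a dynein change from ependymal content. The correlation of Dnah11 with that score over 7 libraries was not past a test (Pearson 0.57, exact two-sided permutation p = 0.177, and 0.353 by Benjamini-Hochberg over 2 relations, Spearman 0.46, p = 0.302). A larger share of ependymal cells and a change of expression within cells, ependymal or other, cannot be told apart by these values, because the score follows the groups. The noise exposure stays open, untested, and whole tissue does not show which cells carried Dnah11.

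Choroid plexus transcripts spread over 4.57 log2 units between libraries. A different share of choroid plexus in each dissected sample may account for this, as each of the 20 markers followed the mean of the others at a correlation of 0.812 or more. Noise is argued against as the cause of the spread, which was wider within Control than within NIHHL, and the exact permutation p between groups was 0.4286.

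Hsd3b1 and Akr1cl had counts in NIHHL libraries alone, and Cyp11a1 had more in NIHHL replicates 1 to 3 than in any Control library but fewer, 9, in NIHHL replicate 4. Adrenal cortex or testis is argued against as the source, because 6 of their genes summed to 9.61 counts over the NIHHL libraries against 157 for Hsd3b1. Ovary cannot be told apart from other sources: 7 ovarian genes were 2.23 CPM higher in NIHHL on average (11.8 against 9.52), without separating the groups. Gkn2 to Gkn1 ratios differed by 1.14 times at most among 5 libraries with both, but Pgc to Gkn1 ratios by 3.31 times. So 1 source of RNA in 1 ratio is argued against for Pgc together with Gkn1, but not for Gkn2 with Gkn1. Other gastric genes were not tested in this way, and where the gastric transcripts came from stays open. Carry-over between samples and index hopping were not tested, and noise exposure was not tested against these for the steroid genes.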
